A study of Mus musculus with 9 samples.

How the data were processed

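Bulk RNA sequencing was done on the hippocampus of mice at postnatal day 21. The 9 samples fall into 3 groups of 3: control, pups exposed to perfluorooctane sulfonate (PFOS) on days 1 to 7 (PFOS P1-7), and pups exposed on days 8 to 14 (PFOS P8-14). Exposure was through the milk of dams given 1 mg/kg of PFOS by gavage each day. The labels do not say whether each sample is a separate animal, and give no litter, sex, batch or date. The p-values therefore measure only the spread between these samples, part of which may be technical.

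The authors deposited 1 table of length-scaled transcript abundance (TPM) per gene symbol, with 1 column per sample. Each deposited TPM column sums to 1000000 within rounding, and the values are rounded to 2 decimals. Per the submitters' processing notes, the tools were bcl2fastq, fastp 0.21.0, STAR 2.5.3a and RSEM 1.3.3 with genome build mm10, and the libraries were stranded and poly(A) selected. The gene annotation and any filter are not given in the sources used here. TPM keep no sequencing depth, so the depth of each sample is unknown and no counting interval was computed.

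All tests used R 4.3.3 and limma 3.58.1 on log2(TPM + 1). Genes with at least 1 TPM in at least 3 of the 9 samples were tested, which left 14336 genes. Of these, 24 have values identical to another symbol. A single linear model with a mean per group and no covariate was fitted, with moderated variances and a mean-variance trend. The 3 pairwise comparisons and a moderated F test of any difference among the 3 groups were two-sided with Benjamini-Hochberg adjustment over all genes. An adjusted p below 0.05 was the threshold. The median standard error of a log2 difference was 0.13, and the median 95% confidence interval reached 0.29 to either side.

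Gene lists for hippocampal cell types, neighbouring tissues, synapse genes and pathways named with PFOS were written from general knowledge. With at least 5 tested members, 43 of the 45 lists could be tested. The mitochondrially encoded genes had fewer, and the list of Y-linked genes and Xist served as a sample check only. Lists were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, a rotation test that does not compare a list with other genes, were run beside it. The same test was applied to 682 mouse Reactome pathways of 15 to 300 tested members from the fgsea 1.28.0 package. Entrez identifiers were found for 99.6% of tested genes. Camera was given the same mean-variance trend as the gene model. That choice was settled after a first look without the trend, so the version without it is reported as an alternative added later. Member counts come from the gene model, over all genes and adjusted over the list alone.

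Genes were named by a fixed rule. For each comparison these were the 5 genes with the smallest p in each direction, since none passed the threshold. They also included the 3 leading members of each list called by camera, and the leading member of any other list where its unadjusted p was below 0.05. Predicted genes were counted and not named, and Xist, Ddx3y, Ttr and Tcf7l2 were read in every sample. Hbb-bs, also in that rule, is not in this file. Gene positions are for mm10 from RefSeq, and transcript lengths are from GENCODE, matched by symbol for 99.1% of tested genes. Chosen later were camera's variance trend, the alternatives named as added later, and the tests and sums named below as chosen after a result was seen. The lists, the naming rule, the other tests and the other settings to vary were fixed before the data were examined.

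The log2 differences of the exposure groups from control were correlated across genes. Because both share the same 3 controls, the same values were computed in 1000 simulated data sets with no group effect, made by rotating the residuals of the fit. The pipeline was also tested on simulated data in which 200 of 14336 genes were shifted, all with a mean log2(TPM + 1) above 3. The noise was drawn for each gene on its own, without trends between libraries. Recovery in genes of lower expression, or with such trends, was not tested. It recovered 45 to 49.5% of 1.5-fold shifts, 84 to 90% of 2-fold shifts and 97.5 to 100% of 4-fold shifts in the 3 comparisons. Figures were drawn with matplotlib 3.10.9.

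The settings varied were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, and median-of-ratios scaling. They also covered quantile normalization, the replicate number as a block, only the compared groups, and limma array weights. Robust moderation, moderation without a trend, an adjusted p threshold of 0.1, an added 1.5-fold limit, and leaving out each sample in turn completed them. Alternatives added after the data were seen were a choroid plexus score as a covariate, removal of each library's trend on transcript length and GC content by loess, both together, and camera without a variance trend. Also added were fits to only the 4 libraries with Ttr below 1000 TPM and only the 5 above it. Count models were not used, because the file holds no counts.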

Results

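Gene expression was measured by bulk RNA sequencing in 9 mouse hippocampus samples taken at postnatal day 21. There were 3 control samples, 3 from pups exposed through nursing on days 1 to 7 (PFOS P1-7) and 3 from pups exposed on days 8 to 14 (PFOS P8-14). PFOS is a persistent perfluorinated surfactant. The stated aim was to find which postnatal window is sensitive to it, so each exposed group was compared with control and the exposed groups with each other. Values are TPM as mean ± SD (n = 3 samples per group), and differences are log2 values with their standard error (SE). The sequencing depth is unknown. Of the gene symbols in the file, 14336 passed the filter, and between 13810 and 14220 symbols per library had at least 1 TPM.

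Libraries differed in choroid plexus markers and in a trend with transcript length. Ttr, which encodes transthyretin and is abundant in choroid plexus, stood at 9446 to 11626 TPM in 5 libraries: control replicate 3, PFOS P1-7 replicates 1 and 3, and PFOS P8-14 replicates 1 and 2. It stood at 35.1 to 107.7 TPM in the other 4. Of the 23 choroid plexus and ependyma markers other than Ttr, 21 were higher in each of the 5 libraries than in each of the 4. Across all tested genes, 590 were higher and 116 were lower in this way, where chance gives 113.8 genes per direction. The deviation of genes from their mean also ran with transcript length. Spearman's rho across genes was -0.34 and -0.40 in control replicates 2 and 3, and -0.15 in PFOS P8-14 replicate 2, but positive in the other libraries, up to 0.36 in PFOS P1-7 replicate 2, so the length trend ran partly with the groups. Genes are not independent replicates. Xist did not exceed 0.03 TPM in any library, whereas the Y-linked gene Ddx3y ranged from 23.1 to 36.1 TPM, and the thalamic marker Tcf7l2 from 3.86 to 7.84 TPM. Single libraries also stood apart in list means of log2 deviations. Control replicate 1 had the highest mean for neocortex and subiculum markers (0.40) and the lowest for myelin genes (-0.63). PFOS P8-14 replicate 1 had the highest for thalamus (0.38) and striatum markers (0.31). Whether dissection differed between samples was not tested.

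**Figure D1:**
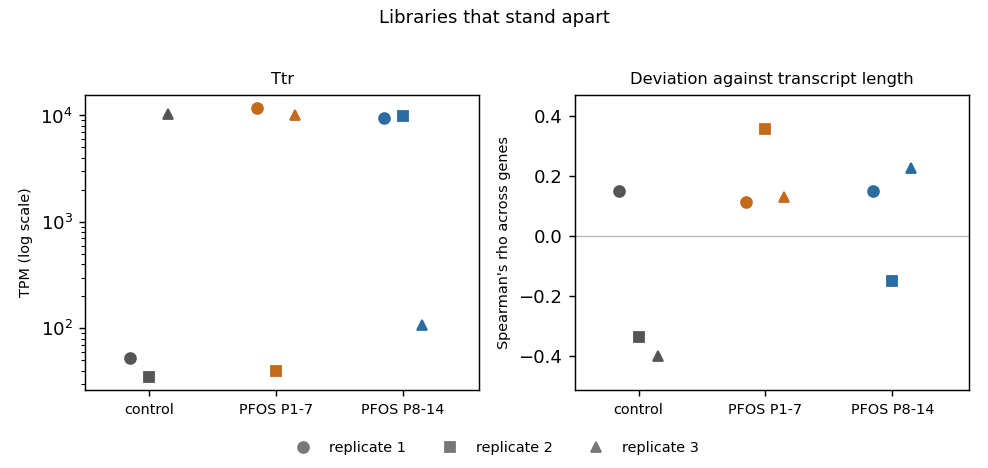
Left, Ttr in TPM on a log scale for each library, with the libraries grouped by control, PFOS P1-7 and PFOS P8-14 and the replicate shown by the symbol. Right, Spearman's rho across genes between transcript length and each library's deviation from the gene means: 5 libraries have Ttr of at least 9446 TPM, and the lowest rho, -0.40, is in control replicate 3.

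The first comparison asked how exposure on days 1 to 7 left the hippocampus at day 21 relative to control. Cytosolic ribosomal protein genes fell as a group, and nuclear-encoded oxidative phosphorylation genes fell with them. Markers of dentate gyrus granule neurons, postsynaptic density genes, voltage-gated ion channel genes, immediate early genes and epigenetic modifier genes rose as groups, relative to other genes by camera. With an estimated correlation, adjusted p = 0.879 for each of these 7 lists, so none of the calls holds there. No single gene passed the threshold in limma (0 genes, smallest adjusted p = 0.181). At an unadjusted p below 0.05 there were 2627 genes, 1797 higher and 830 lower, where a uniform spread of p-values gives 716.8. The median log2 difference of all tested genes was 0.09, and 0.01 with median-of-ratios scaling. List medians and counts of higher members below are therefore to be read against 0.09 and not against 0. In other fits that level differed. It was 0.0057 with the length and GC trend removed, and 0.11 and 0.07 without control replicates 1 and 3.

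Of 79 ribosomal protein genes, 78 were lower in PFOS P1-7, with a median log2 difference of -0.30 (adjusted p = 1.9e-28; adjusted p = 0.879 with an estimated correlation). None of them passed over all genes; 16 were lower when adjusted over the list alone. Rplp1, a ribosomal stalk protein gene on chromosome 9 (61913283 to 61914510), stood at 2189 ± 186 TPM in control and 1382 ± 231 TPM in PFOS P1-7. Rpl41 stood at 1954 ± 323 and 1318 ± 71.6 TPM, and Rpl10a at 477 ± 45.9 and 367 ± 3.51 TPM. The list's median transcript length is 696.5 bases, and its genes were most raised in control replicates 2 and 3, the libraries with the most negative length trend. Without control replicate 2 the median was -0.19, and the call held. Of 76 oxidative phosphorylation genes, 60 were lower, with a median of -0.13 (adjusted p = 3.8e-11; adjusted p = 0.879 with an estimated correlation) and 2 lower adjusted over the list alone. Their median transcript length is 671 bases. Ndufb5, a complex I subunit gene, stood at 229 ± 20.8 in control and 168 ± 4.16 TPM in PFOS P1-7, Atp5d at 856 ± 21.3 and 676 ± 34.4 TPM, and Uqcr11 at 1782 ± 356 and 1209 ± 42.5 TPM.

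Among neuronal groups, 19 of 20 dentate granule neuron markers were higher, with a median of 0.28 (adjusted p = 7.8e-04; adjusted p = 0.879 with an estimated correlation). One of them, Dsp, the desmosomal protein desmoplakin, passed when adjusted over the list alone, at 11.4 ± 1.31 TPM in control and 18.0 ± 0.340 TPM in PFOS P1-7. Ahcyl2 stood at 96.2 ± 4.93 and 115 ± 6.59 TPM, and Dock10 at 22.2 ± 3.27 and 29.9 ± 2.52 TPM. Of 30 postsynaptic density and plasticity genes, 28 were higher, with a median of 0.25 (adjusted p = 7.8e-04; adjusted p = 0.879 with an estimated correlation) and 4 adjusted over the list alone. Ppp3ca, the catalytic subunit of calcineurin, stood at 940.1 ± 42.7 and 1227 ± 54.9 TPM, and Dlgap1, a scaffold protein gene, at 232 ± 16.1 and 288 ± 19.7 TPM. Of 32 voltage-gated ion channel genes, 30 were higher, with a median of 0.25 (adjusted p = 0.00448; adjusted p = 0.879 with an estimated correlation) and 1 adjusted over the list alone. Kcna1, a potassium channel gene, stood at 53.2 ± 3.78 and 71.8 ± 0.867 TPM, and Kcnq5 at 29.1 ± 6.27 and 41.1 ± 4.57 TPM. The ion channel call was lost without PFOS P1-7 replicate 2 (adjusted p = 0.0836), and the median was 0.39 without control replicate 1 and 0.16 without control replicate 3. With the length and GC trend removed the call was lost too (adjusted p = 0.0627), with a median of 0.10 against 0.0057 for all tested genes in that fit. Median transcript lengths of these lists are 3192, 3765 and 4887 bases. Control replicate 1 stood among the exposed libraries, at 0.10 for the postsynaptic and 0.13 for the ion channel list, above PFOS P1-7 replicates 1 and 3 (0.07 and 0.06, and 0.08 and 0.0045). Control replicates 2 and 3 stood at -0.28 and -0.30, and at -0.27 and -0.35.

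Of 35 immediate early genes, 26 were higher in PFOS P1-7 than in control, with a median of 0.22 (adjusted p = 0.0160; adjusted p = 0.879 with an estimated correlation). Adjusted over the list alone, 11 were higher. Nr4a1, an orphan nuclear receptor gene on chromosome 15 (101253902 to 101274795), stood at 47.7 ± 2.27 TPM in control and 72.2 ± 10.4 TPM in PFOS P1-7. Ptgs2, which encodes cyclooxygenase-2, stood at 11.9 ± 0.757 and 16.8 ± 0.448 TPM, and Egr3 at 52.5 ± 21.8 and 91.7 ± 8.80 TPM. The call was lost without control replicate 1 (adjusted p = 0.107) or PFOS P1-7 replicate 2 (adjusted p = 0.0836), and the median was 0.37 without PFOS P1-7 replicate 1. Of 28 epigenetic DNA methylation and histone modifier genes, 25 were higher, with a median of 0.21 (adjusted p = 0.0325; adjusted p = 0.879 with an estimated correlation) and 0 adjusted over the list alone in limma, against 10 at an unadjusted p below 0.05. Arid1b, a chromatin remodelling subunit gene, stood at 21.8 ± 4.17 and 28.1 ± 1.58 TPM. This call was lost without control replicate 2 (adjusted p = 0.0876) or 3 (0.115) and without PFOS P1-7 replicate 1 (0.0718) or 2 (0.0800). Control replicate 1 stood at 0.11, above PFOS P1-7 replicates 1 and 3 (0.08 and 0.04), and control replicates 2 and 3 at -0.25 and -0.27. The median was 0.32 without control replicate 1, and the call was lost with the length and GC trend removed (adjusted p = 0.132).

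The genes with the smallest p all have an adjusted p of 0.181. Atp11b, a phospholipid flippase gene on chromosome 3 (35754044 to 35856276), stood at 41.4 ± 2.35 TPM in control and 59.1 ± 2.47 TPM in PFOS P1-7, a log2 difference of 0.51 (SE 0.07). Npm3, a histone chaperone gene of the nucleophosmin family on chromosome 19 (45747734 to 45749565), stood at 34.0 ± 4.94 and 18.6 ± 0.606 TPM, a difference of -0.83 (SE 0.11). On the higher side, Secisbp2l stood at 74.4 ± 4.11 and 104 ± 6.13 TPM, and Thbs4, an extracellular matrix glycoprotein gene, at 11.2 ± 0.512 and 17.2 ± 0.807 TPM. On the lower side, Ttc9b stood at 219 ± 24.3 and 137 ± 7.47 TPM, Gng13 at 59.7 ± 9.22 and 34.5 ± 1.95 TPM, Ctla2a at 15.5 ± 0.716 and 9.12 ± 1.16 TPM, and Emc10 at 278 ± 20.7 and 209 ± 2.38 TPM. DXBay18, on the X chromosome, was listed at 0 in each control and at 2.13 to 2.43 TPM in PFOS P1-7; it belongs to a multi-copy family, so its assignment is uncertain.

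Among lists that camera did not call here, Klf9, a transcription factor gene responsive to thyroid hormone and glucocorticoids, stood at 118 ± 31.0 TPM in control and 177 ± 6.44 TPM in PFOS P1-7. Nr3c2, the mineralocorticoid receptor gene, stood at 55.6 ± 12.5 and 86.4 ± 3.12 TPM, and the long-chain acyl-CoA synthetase genes Acsl1 and Acsl3 at 33.02 ± 1.45 and 42.3 ± 2.42, and 109 ± 5.27 and 141 ± 6.85 TPM. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, stood at 35.1 ± 3.08 and 43.97 ± 1.38 TPM. S100a10 stood at 58.9 ± 6.25 and 36.3 ± 6.19 TPM, and the tight junction gene Cldn5 at 116 ± 8.85 and 86.3 ± 11.996 TPM. None of these passed over all genes (adjusted p from 0.181 to 0.188). Reactome gave 9 pathways up and 43 down. Eukaryotic Translation Elongation, of which 88.2% of members are in the ribosomal list, had a median of -0.28 (adjusted p = 6.1e-26; adjusted p = 0.582 with an estimated correlation), and Netrin-1 signaling had a median of 0.20 (adjusted p = 0.00403; adjusted p = 0.928 with an estimated correlation).

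The count of 0 genes depended on single libraries and on their weights: without control replicate 1, limma called 2658 genes, 2017 of them higher, and with array weights it called 2914, 2152 of them higher. Control replicate 1 is the only control with a positive length trend (rho 0.15). Without it the controls stood at -0.34 and -0.40 and PFOS P1-7 at 0.11 to 0.36, so exposure and the length trend cannot be told apart there. No fit without it was run with that trend removed. Fry called 0 lists in 1 direction (smallest adjusted p = 0.119, against 7 lists by camera) and 10 in its test of change in either direction, each of the 9 other ways to split these 6 samples gave at least 7 camera lists, and median-of-ratios scaling took the share of higher genes at an unadjusted p below 0.05 from 68.4% to 42.3%, and removal of the length and GC trend took it to 48.9% (1009 higher and 1053 lower).

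**Figure D2:**
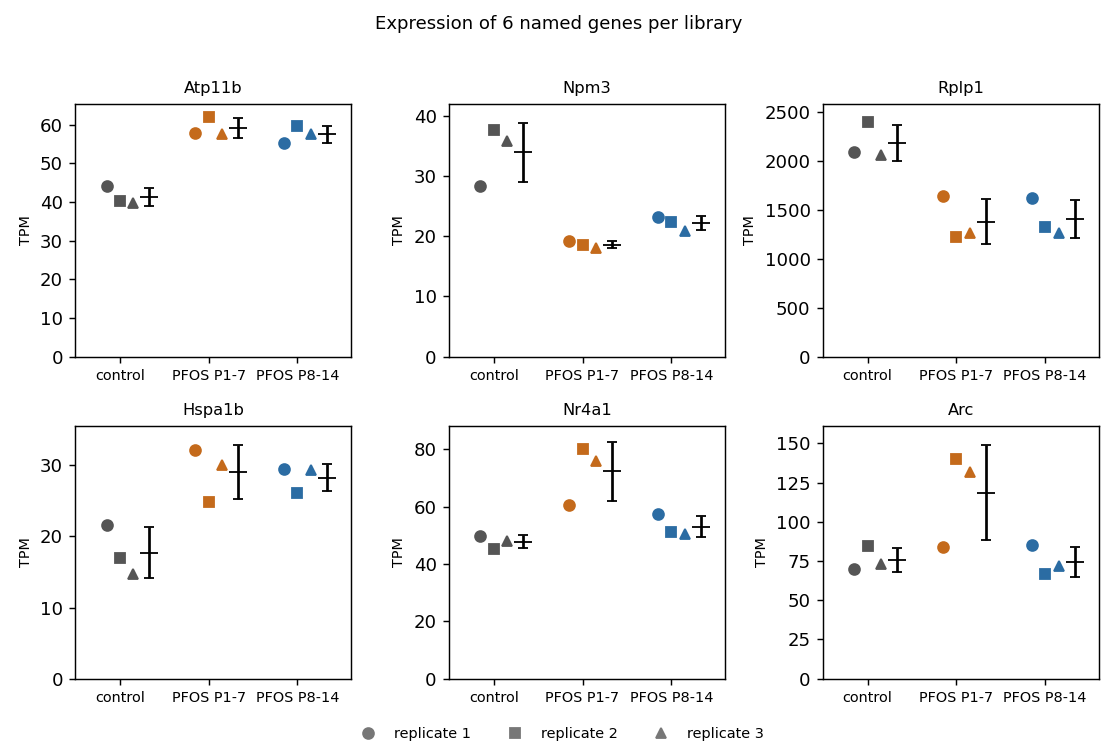
TPM of 6 named genes in each library, with the group on the horizontal axis, the replicate shown by the symbol, and the group mean ± SD (n = 3) as a bar beside the points. Atp11b and Hspa1b are higher and Npm3 and Rplp1 lower in every exposed library than in every control library, whereas Nr4a1 and Arc have their highest group mean in PFOS P1-7 (72.2 and 119 TPM).

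The second comparison asked the same of exposure on days 8 to 14. Ribosomal protein and oxidative phosphorylation genes fell as groups here too, and dentate granule neuron, postsynaptic density, ion channel and epigenetic modifier genes rose. Presynaptic genes, CA3 pyramidal neuron markers, neurotrophin signalling genes and choroid plexus markers also rose by camera, and interferon-stimulated genes and blood cell genes fell. Microglia markers were called lower relative to other genes, with as many members higher as lower. Camera did not call them in PFOS P1-7 against control (median 0.04, adjusted p = 0.162), although 3 members were lower there adjusted over the list alone. Between the exposed groups they were not called either (adjusted p = 0.486). In PFOS P1-7 against control the presynaptic, CA3, neurotrophin and choroid plexus lists were not called but had medians of 0.21, 0.18, 0.29 and 1.45 (adjusted p = 0.144, 0.154, 0.0808 and 0.144), and in the direct comparison of the exposed groups they were not called either (adjusted p = 0.444, 0.414, 0.913 and 0.545). With an estimated correlation none of the 13 calls in PFOS P8-14 holds: the adjusted p is 0.809 for blood cell genes, 0.874 for the ribosomal, oxidative phosphorylation, CA3 and neurotrophin lists, and 0.935 for the others. No single gene passed in limma (0 genes, smallest adjusted p = 0.424), and 1573 had an unadjusted p below 0.05, 907 higher and 666 lower. The median log2 difference of all tested genes was 0.06 here, the level against which list medians are to be read. With the length and GC trend removed that level was 0.0058.

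Of 79 ribosomal protein genes, 75 were lower in PFOS P8-14, with a median of -0.25 (adjusted p = 3.8e-26; adjusted p = 0.874 with an estimated correlation) and 5 lower adjusted over the list alone. Rplp1 stood at 1409 ± 192 TPM against 2189 ± 186 TPM in control. Of 76 oxidative phosphorylation genes, 52 were lower, with a median of -0.09 (adjusted p = 2.0e-06; adjusted p = 0.874 with an estimated correlation) and 0 adjusted over the list alone in limma, against 14 lower and 2 higher at an unadjusted p below 0.05. Ndufb5 stood at 175 ± 7.24 against 229 ± 20.8 TPM and Ndufc1 at 316 ± 34.2 against 458 ± 77.7 TPM. With the length and GC trend removed the oxidative phosphorylation call was lost (-0.05, adjusted p = 0.0712), and without PFOS P8-14 replicate 2, which has a negative length trend, the median was -0.13.

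**Figure D3:**
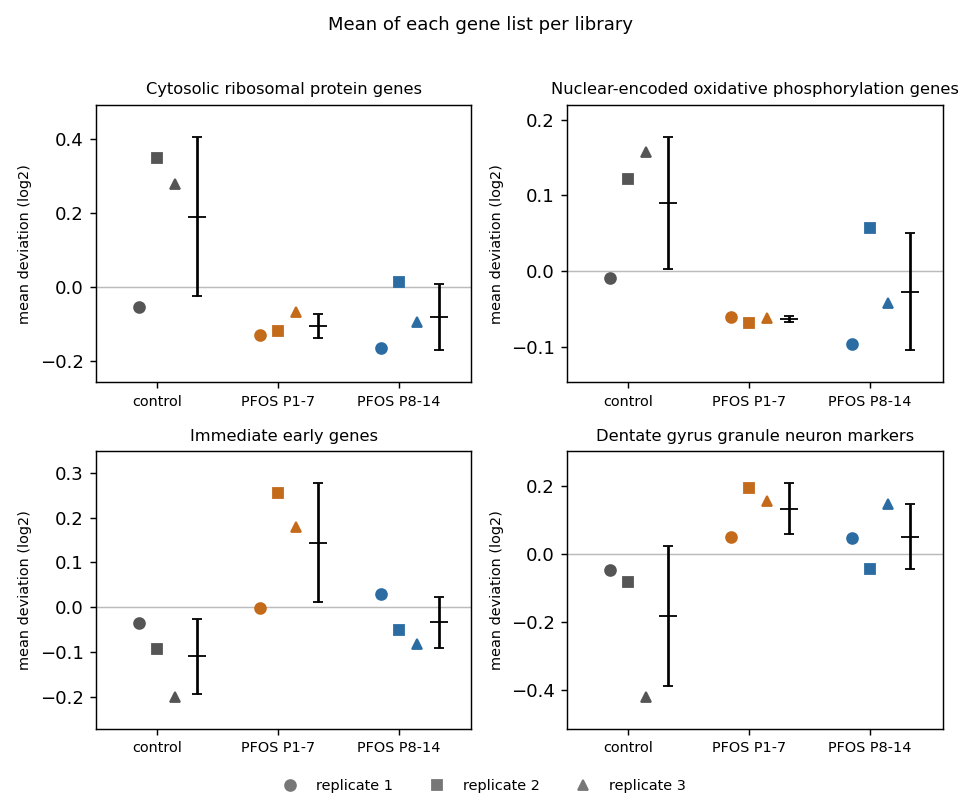
Mean log2 deviation of each list from the gene means in each library, for 4 lists, with the group on the horizontal axis, the replicate shown by the symbol and the group mean ± SD (n = 3) as a bar. The ribosomal list stands at 0.35 and 0.28 in control replicates 2 and 3 and at -0.06 in control replicate 1, inside the range of the exposed libraries.

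Of 20 dentate granule neuron markers, 18 were higher, with a median of 0.21 (adjusted p = 0.00442; adjusted p = 0.935 with an estimated correlation). The call was lost without control replicate 3 (adjusted p = 0.0764; median 0.12) or PFOS P8-14 replicate 3 (0.0657). Dsp stood at 15.8 ± 0.646 TPM against 11.4 ± 1.31 TPM in control. Of 30 postsynaptic density genes, 27 were higher, with a median of 0.21 (adjusted p = 0.00442; adjusted p = 0.935 with an estimated correlation). This call too was lost without control replicate 3 (adjusted p = 0.0560) or PFOS P8-14 replicate 3 (0.103). Control replicate 1 stood at 0.10 for this list, above PFOS P8-14 replicates 1 and 2 (0.06 and -0.07) and below replicate 3 (0.15). Ppp3ca stood at 1158 ± 149.9 against 940.1 ± 42.7 TPM. Of 32 presynaptic vesicle and release genes, 28 were higher, with a median of 0.18 (adjusted p = 0.0171; adjusted p = 0.935 with an estimated correlation). Syt1, a calcium sensor of vesicle release, stood at 829 ± 58.6 against 701 ± 93.7 TPM. The presynaptic call was lost without control replicate 2 or 3 or PFOS P8-14 replicate 3 (adjusted p = 0.116, 0.192 and 0.174), and its median was 0.34 without control replicate 1, which stood at 0.21, above every PFOS P8-14 library (up to 0.14). Of 32 ion channel genes, 29 were higher, with a median of 0.18 (adjusted p = 0.0142; adjusted p = 0.935 with an estimated correlation). Kcna1 stood at 66.1 ± 3.93 against 53.2 ± 3.78 TPM. The ion channel call was lost without control replicate 3 (adjusted p = 0.145) or PFOS P8-14 replicate 3 (0.215), and with the length and GC trend removed (0.159), and its median was 0.32 without control replicate 1. That library stood at 0.13, above PFOS P8-14 replicates 1 and 2 (0.08 and -0.08) and below replicate 3 (0.16).

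CA3 pyramidal neuron markers were higher in 11 of 14 cases, with a median of 0.25 (adjusted p = 0.0200; adjusted p = 0.874 with an estimated correlation). Pvrl3, the cell adhesion molecule nectin-3, stood at 30.3 ± 3.27 TPM against 21.9 ± 1.45 TPM in control. The CA3 call was lost without control replicate 1 (adjusted p = 0.294), PFOS P8-14 replicate 2 (0.113) or PFOS P8-14 replicate 3 (0.0840). Of 24 neurotrophin and growth factor signalling genes, 22 were higher, with a median of 0.25 (adjusted p = 0.0200; adjusted p = 0.874 with an estimated correlation). Igf1 stood at 4.74 ± 0.636 against 3.38 ± 0.182 TPM. This call was lost without control replicate 1 (adjusted p = 0.0590) or PFOS P8-14 replicate 1 (0.0686). Of 28 epigenetic modifier genes, 25 were higher, with a median of 0.17 (adjusted p = 0.0200; adjusted p = 0.935 with an estimated correlation). Tet2, which oxidizes methylated cytosine, stood at 13.6 ± 0.331 against 10.2 ± 1.72 TPM. The epigenetic call was lost without control replicate 2 (adjusted p = 0.0709) or 3 (0.145), PFOS P8-14 replicate 1 (0.0856) or 3 (0.0732), with the length and GC trend removed (0.0759), and its median was 0.29 without control replicate 1. That library stood at 0.11, above PFOS P8-14 replicates 2 and 3 (-0.06 and 0.07) and below replicate 1 (0.13).

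Groups that come from other cells were mixed. Of 24 choroid plexus markers, 22 were higher in PFOS P8-14, with a median of 1.29 (adjusted p = 0.0200; adjusted p = 0.935 with an estimated correlation). They moved with Ttr rather than with exposure alone, since 1 control and 4 exposed libraries carry the high level. This call was lost without control replicate 1 (adjusted p = 0.867), control replicate 2 (0.162), PFOS P8-14 replicate 1 (0.203) or PFOS P8-14 replicate 2 (0.402), and the median was 2.01 without control replicate 3 and 2.27 without PFOS P8-14 replicate 3. Of 26 interferon-stimulated genes, 21 were lower, with a median of -0.17 (adjusted p = 0.0126; adjusted p = 0.935 with an estimated correlation). Their level was raised in control replicate 2, by 0.80 on average, and without it the median turned to 0.21 (adjusted p = 0.0709). Among the 5 libraries with high Ttr the median was 0.36, but these hold 1 control, replicate 3, with a list mean of -0.43, so the direction rests on that library. The call was also lost without PFOS P8-14 replicate 3 (adjusted p = 0.0790) or with the length and GC trend removed (0.0712), and the median was -0.28 and -0.47 without control replicates 1 and 3. Of 5 blood cell genes, 4 were lower, with a median of -0.89 (adjusted p = 0.0126; adjusted p = 0.809 with an estimated correlation) and 2 adjusted over the list alone. Hbb-b1, a beta-globin gene, stood at 157 ± 17.9 against 309 ± 53.98 TPM, and the list median was -0.52 and -0.40 without control replicates 2 and 3. Hbb-bs, another beta-globin gene, is not in this file, so how fully Hbb-b1 holds the beta-globin reads is unknown. Of 22 microglia markers, 11 were lower and 11 higher, with a median of -0.02 (adjusted p = 0.0278; adjusted p = 0.935 with an estimated correlation) and 2 adjusted over the list alone. The complement genes C1qb and C1qa stood at 72.4 ± 3.05 against 97.9 ± 9.47, and 80.4 ± 3.66 against 98.8 ± 7.19 TPM. The microglia call was lost without control replicate 1 (0.05, adjusted p = 0.431) or PFOS P8-14 replicate 1 (0.03, 0.146), and the median was -0.05 and -0.08 without control replicates 2 and 3, and -0.01 and -0.07 without PFOS P8-14 replicates 2 and 3. With the length and GC trend removed the microglia call was lost as well (adjusted p = 0.217). With the choroid plexus score as a covariate the choroid plexus, interferon, neurotrophin and microglia calls were lost (adjusted p = 0.471, 0.0742, 0.221 and 0.265).

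Of the single genes, Atp11b again had the smallest p among those higher, at 57.5 ± 2.15 TPM against 41.4 ± 2.35 TPM in control. Hspa1b, an inducible heat shock protein gene on chromosome 17 (34956429 to 34959238), stood at 28.3 ± 1.91 against 17.7 ± 3.54 TPM, a log2 difference of 0.66 (SE 0.14). Ccbe1 stood at 17.2 ± 1.23 against 10.7 ± 1.68 TPM, Tma16 at 20.1 ± 1.10 against 13.0 ± 1.92 TPM, and Cwc22 at 17.3 ± 0.382 against 12.6 ± 0.570 TPM. Tnfrsf25, a death receptor gene on chromosome 4 (152115528 to 152120119), stood at 9.41 ± 1.51 against 19.1 ± 3.49 TPM, a difference of -0.94 (SE 0.15). Hes5, a Notch effector gene, stood at 16.0 ± 0.349 against 24.9 ± 2.61 TPM, Npm3 at 22.2 ± 1.17 against 34.0 ± 4.94 TPM, and Clk1, a kinase of splicing factors, at 96.2 ± 3.04 against 122.6 ± 6.77 TPM. Ccl27b stood at 5.54 ± 0.367 against 11.6 ± 2.41 TPM, but its values are identical to those of another symbol and cannot be assigned to it alone. All have an adjusted p of 0.424. Reactome gave 8 pathways up and 41 down, with Netrin-1 signaling at a median of 0.21 (adjusted p = 8.7e-04; adjusted p = 0.923 with an estimated correlation) and Axon guidance at 0.13 (adjusted p = 0.0278; adjusted p = 0.923 with an estimated correlation).

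Here too the 0 was not stable: without control replicate 1 limma called 1741 genes, 1253 of them higher, and with array weights 1053, 653 of them higher. The controls left then both have a negative length trend (rho -0.34 and -0.40). PFOS P8-14 replicates 1 and 3 have a positive one (0.15 and 0.23) and replicate 2 a negative one (-0.15). The 1741 genes may therefore reflect that trend, which was not tested. Fry called 0 lists (smallest adjusted p = 0.196, against 13 by camera), 4 of the 9 other splits of these samples gave at least 13 lists, and median-of-ratios scaling took the share of higher genes at an unadjusted p below 0.05 from 57.7% to 36.9%, and removal of the length and GC trend took it to 46.7% (766 higher and 875 lower).

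The third comparison tested the difference between the exposure windows directly. Immediate early genes, which are induced by neuronal activity, were lower after exposure on days 8 to 14 than after days 1 to 7, as were interferon-stimulated, circadian clock and blood cell genes. Leptomeningeal and fibroblast markers, oxidative phosphorylation, ribosomal protein and glycolysis genes and GABAergic interneuron markers were higher by camera. With an estimated correlation none of these 9 calls holds (adjusted p from 0.903 to 0.946). No gene passed in limma (0 genes, smallest adjusted p = 0.9998), and 158 had an unadjusted p below 0.05, fewer than the 716.8 of a uniform spread. The median log2 difference of all tested genes was -0.03.

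Of 35 immediate early genes, 28 were lower in PFOS P8-14, with a median of -0.17 (adjusted p = 4.7e-06; adjusted p = 0.903 with an estimated correlation). In limma 0 passed when adjusted over the list alone, and 8 were lower at an unadjusted p below 0.05. Nr4a1 stood at 53.0 ± 3.77 TPM against 72.2 ± 10.4 TPM in PFOS P1-7, and at 47.7 ± 2.27 TPM in control. Arc, a synaptic plasticity gene on chromosome 15 (74669081 to 74672570), stood at 74.5 ± 9.55 against 119 ± 30.1 TPM, and at 75.9 ± 7.64 TPM in control. Egr1 stood at 104 ± 2.46 against 145 ± 32.6 TPM, and at 104 ± 9.30 TPM in control. The list's call was kept without each library, with a median of -0.28 without PFOS P1-7 replicate 1. In PFOS P8-14 against control the list had a median of 0.08 and was not called (adjusted p = 0.718).

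All 19 leptomeningeal and fibroblast markers were higher in PFOS P8-14, with a median of 0.23 (adjusted p = 1.7e-05; adjusted p = 0.930 with an estimated correlation). Fmod, the matrix proteoglycan fibromodulin, stood at 8.62 ± 3.87 against 4.79 ± 1.89 TPM. That call was lost without PFOS P1-7 replicate 2 (0.06, adjusted p = 0.4996) or PFOS P8-14 replicate 1 (0.01, 0.366), and the median was 0.37 without PFOS P1-7 replicate 1 and 0.47 without PFOS P8-14 replicate 3. Among the exposed libraries this list followed the Ttr level, with mean deviations of 0.34, 0.10, 0.70 and 0.25 at the high level and -0.60 and -0.39 at the low level. The controls did not, with -0.15 in control replicate 3 at the high level and -0.15 and -0.11 in control replicates 1 and 2 at the low level. Of 26 interferon-stimulated genes, 25 were lower, with a median of -0.21 (adjusted p = 0.00273; adjusted p = 0.946 with an estimated correlation). Stat2 stood at 14.2 ± 0.670 against 16.6 ± 0.694 TPM. The interferon call was lost without PFOS P1-7 replicate 1 (adjusted p = 0.101) or PFOS P8-14 replicate 3 (0.129). All 5 blood cell genes were lower, with a median of -0.42 (adjusted p = 0.0345; adjusted p = 0.903 with an estimated correlation). Alas2, the erythroid enzyme of heme synthesis, stood at 7.88 ± 2.40 against 11.6 ± 2.27 TPM. The blood call was lost without PFOS P1-7 replicates 2 or 3 (adjusted p = 0.107 and 0.0886) or PFOS P8-14 replicates 2 or 3 (0.0918 and 0.0514), and the median was -0.66 without PFOS P1-7 replicate 1. Hba-a1 cannot be read alone, since it is listed at 0 in control replicate 1 and PFOS P8-14 replicate 1, where its near-identical copy Hba-a2 stands at 1835 and 1515 TPM.

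Without a variance trend in camera the blood, circadian, glycolysis and GABAergic calls were lost (adjusted p = 0.0530, 0.0523, 0.0530 and 0.0607), and with the choroid plexus score as a covariate the blood, glycolysis and GABAergic calls were lost (0.0556, 0.0556 and 0.0710). The remaining lists had medians from -0.09 to 0.05. Of 76 oxidative phosphorylation genes, 59 were higher in PFOS P8-14, with a median of 0.03 (adjusted p = 5.1e-05; adjusted p = 0.930 with an estimated correlation). This call was lost without PFOS P8-14 replicate 2 (-0.01, adjusted p = 0.669), and the median was 0.07 without PFOS P8-14 replicate 1. Of 79 ribosomal protein genes, 53 were higher, with a median of 0.02 (adjusted p = 0.00457; adjusted p = 0.946 with an estimated correlation). The direction turned without PFOS P8-14 replicate 2 (-0.03, adjusted p = 0.906) and the call was lost without PFOS P1-7 replicate 2 (0.01, 0.124). Without PFOS P1-7 replicates 1 and 3 the ribosomal median was 0.0018 and 0.04, and without PFOS P8-14 replicate 1 it was 0.06. With the length and GC trend removed the ribosomal, glycolysis and GABAergic calls were lost (adjusted p = 0.217, 0.217 and 0.0967), and the blood cell list had too few members with a known length to be tested. Of 18 circadian clock genes, 15 were lower, with a median of -0.09 (adjusted p = 0.0341; adjusted p = 0.930 with an estimated correlation). Per2 stood at 16.3 ± 1.33 against 18.7 ± 0.166 TPM, and the call was lost without PFOS P1-7 replicate 2 (adjusted p = 0.286) or PFOS P8-14 replicate 2 (0.265). Of 22 glycolysis genes, 18 were higher, with a median of 0.04 (adjusted p = 0.0345; adjusted p = 0.946 with an estimated correlation). The glycolysis call was lost without PFOS P1-7 replicate 3 (adjusted p = 0.663), PFOS P8-14 replicate 1 (0.0693) or 3 (0.204), and the median was 0.07 without PFOS P1-7 replicate 2. Of 22 GABAergic interneuron markers, 13 were higher, with a median of 0.05 (adjusted p = 0.0497; adjusted p = 0.946 with an estimated correlation). Calb2, which encodes calretinin, stood at 105 ± 40.0 against 63.8 ± 13.9 TPM. The GABAergic call was lost without control replicate 2 or 3, PFOS P1-7 replicate 1 or 3, or any PFOS P8-14 replicate, with adjusted p from 0.0546 to 0.837, and the median was 0.07 without PFOS P1-7 replicate 2.

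Of the single genes, Pdcd2 stood at 17.5 ± 1.33 TPM in PFOS P8-14 and 12.1 ± 1.21 TPM in PFOS P1-7, Uxt at 14.1 ± 0.762 and 10.2 ± 0.952 TPM, Gmfg at 3.22 ± 0.558 and 1.64 ± 0.393 TPM, Bex1 at 139 ± 10.4 and 113 ± 5.89 TPM, and Gpn2 at 13.8 ± 0.650 and 10.6 ± 0.452 TPM. Samsn1 stood at 0.850 ± 0.282 and 2.03 ± 0.393 TPM, and Tnfrsf25 at 9.41 ± 1.51 and 14.2 ± 1.25 TPM. All have an adjusted p of 0.9998. Reactome gave 10 pathways up and 0 down by camera, with Respiratory electron transport at a median of 0.04 (adjusted p = 0.00382; adjusted p = 0.977 with an estimated correlation) and Collagen formation at 0.05 (adjusted p = 0.0215; adjusted p = 0.977 with an estimated correlation). Neither had a member at an unadjusted p below 0.05.

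The 0 genes here did not change without any single library or with array weights, and fry called 0 lists (smallest adjusted p = 0.999, against 9 by camera). Of the 9 other splits of these samples, 5 gave at least 9 lists and 7 gave at least 158 genes at an unadjusted p below 0.05.

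Across the 3 groups the moderated F test in limma also called 0 genes (smallest adjusted p = 0.362), with 1622 at an unadjusted p below 0.05. It called 1493 without control replicate 1, which leaves only controls with a negative length trend, and 1532 with array weights. The log2 differences of the exposure groups from control ran together across genes, with Pearson's r of 0.834 and Spearman's rho of 0.833, and 84.5% of genes had the same sign. Both share the same controls, which alone raises these values, and in simulated data with no effect r had a median of 0.554 and a 95% range of -0.46 to 0.957. The covariance, 0.0520, was reached in 12.1% of the simulations. Leaving out each library in turn gave r from 0.721 to 0.898.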

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

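In this part, the tests chosen only after the result was seen are those of choroid plexus tissue and of PFOS on its markers, those of whether 1 library decides a list, the regroupings of libraries for the ribosomal and immediate early lists, and the fits with the choroid plexus score or without the length and GC trend. The random lists matched to the ribosomal list also belong to these, since that list was picked after the results were seen.

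Gene lists that differed between the exposure windows by camera are listed with the median log2 difference of PFOS P8-14 from PFOS P1-7 (3 samples against 3), and none of the calls holds with an estimated correlation (adjusted p from 0.903 to 0.946). The list of immediate early genes differed by -0.17. Leptomeningeal and fibroblast markers differed by 0.23. Oxidative phosphorylation genes differed by 0.0312. Interferon-stimulated genes differed by -0.21. Ribosomal protein genes differed by 0.0201. Circadian clock genes differed by -0.0885. Blood cell genes differed by -0.42. Glycolysis genes differed by 0.0402. GABAergic interneuron markers differed by 0.0482.

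The counts were set against the 10 ways to split each pair of groups, the real split included, which are too few for a share under 0.05. For called genes the real counts are 0, so every split gives as many and these counts say nothing about chance. In PFOS P1-7 against control, 10 splits gave as many called genes (real 0, highest other 0), 2 as many genes at an unadjusted p below 0.05 (real 2627, highest other 3111) and 10 as many lists (real 7, highest other 20). In PFOS P8-14 against control, 10 gave as many called genes (real 0, highest other 735), 3 as many at an unadjusted p below 0.05 (real 1573, highest other 3796) and 5 as many lists (real 13, highest other 15). In PFOS P8-14 against PFOS P1-7, 10 gave as many called genes (real 0, highest other 0), 8 as many at an unadjusted p below 0.05 (real 158, highest other 1698) and 6 as many lists (real 9, highest other 14). Splits by Ttr level gave 20 and 14 lists in the comparisons of PFOS P1-7 and PFOS P8-14 with control, at least as many as the real ones, and 952 and 725 genes at an unadjusted p below 0.05, fewer than the real ones. For the F test, 100 of 100 drawn splits of the 9 samples gave as many called genes (real 0, highest other 2479), which again says nothing about chance. At an unadjusted p below 0.05, 10 of 100 gave as many (real 1622, highest other 5370), so chance is not excluded for that count. The splits that call 735 and 2479 genes may point to a structure of the samples other than the groups. The split with 735 set control replicate 1 and PFOS P8-14 replicates 1 and 3 against control replicates 2 and 3 and PFOS P8-14 replicate 2. It therefore ran with the sign of the length trend (rho of 0.15 to 0.23 against -0.40 to -0.15). Yet 735 arose in 1 of 9 other splits, and how often such a highest count arises with no structure was not tested.

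The ribosomal protein list was lower in both exposed groups than in control. Of 10000 random lists matched on length and expression, 0 had a median as low as -0.30 or -0.25. Their genes were drawn independently, while the list's members move together (estimated correlation 0.457), so this count cannot exclude a length trend. The matched lists had a median of -0.10 and -0.03, so the trend may account for part. With the length and GC trend removed, 84.5% and 90.6% of the list median was kept. The median of all tested genes moved as well, from 0.09 to 0.0057 and from 0.06 to 0.0058. Relative to all genes, less of the fall was therefore kept than these percentages. The list medians left, -0.25 and -0.23, still argue against the trend shared by all genes as the whole cause. Choroid plexus RNA is argued against too, with 100.4% of the fall kept with its score as a covariate, and so is any 1 control library as the whole cause, with 65.4% kept without control replicate 2, the lowest. Control replicates 2 and 3 stood at 0.35 and 0.28, and control replicate 1 at -0.06, inside the range of the exposed libraries. Leaving out 1 library cannot exclude that control replicates 2 and 3 together carry the fall. Of the 84 ways to pick 3 of the 9 libraries, 2 splits gave a mean difference as large as -0.28 (highest other 0.318, for control replicates 2 and 3 with PFOS P8-14 replicate 2). Those 3 libraries are the ones with a negative length trend, so the list separated libraries more by the sign of that trend than by exposure. The list was picked from 43 after they were seen, and 84 splits are too few for a share under 0.05 over 43 lists. Chance, a contribution of the length trend, litter, RNA quality, batch, depth and a response to PFOS stay open.

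The immediate early gene list was lower in PFOS P8-14 than in PFOS P1-7. The length trend is argued against as the whole cause, since 91.6% of the difference was kept with the length and GC trend removed, and so is any 1 exposed library, with 77.3% kept without PFOS P1-7 replicate 2, the lowest. The groups overlap, with PFOS P1-7 replicate 1 at -0.0016 and PFOS P8-14 replicate 1 at 0.03. PFOS P1-7 replicates 2 and 3 stood at 0.26 and 0.18, and leaving out 1 library cannot exclude that these 2 carry the difference. Choroid plexus RNA was nearly balanced, since both exposed groups hold 2 high libraries and 1 low, with mean marker deviations of 0.46 in PFOS P1-7 and 0.39 in PFOS P8-14. This balance argues against choroid plexus RNA as the cause. With the choroid plexus score as a covariate 99.98% was kept, but the covariate moved this comparison by a median of only 0.00262 per gene, so that fit itself decides nothing. Of the 10 splits of the 6 exposed samples, 2 gave a mean difference as large as -0.18 (highest other 0.199, for PFOS P1-7 replicate 1 with PFOS P8-14 replicates 2 and 3), and 10 splits are too few for a share under 0.05. These genes respond within minutes to handling and arousal, and how the animals were handled before sampling is not given in the sources used here. A difference at collection, chance, litter and the exposure window may each account for the lower list.

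Choroid plexus markers were high in 5 of the 9 libraries. PFOS as the cause is argued against, since 3 libraries run against it, 1 control at the high Ttr level and 2 exposed at the low level. Choroid plexus tissue carried along in dissection is a candidate explanation: 21 of 23 markers other than Ttr, which defined the levels, were higher in each of the 5 libraries than in each of the other 4, and Ttr reached 0.945 to 1.16% of all TPM there. In control replicate 3, Ttr was 1.02 times the mean of the exposed high libraries while the other separated markers had a median of 0.518 times, which stays unexplained.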

How the results depend on the processing

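In this part, the tests chosen only after the data were seen are those with the choroid plexus score, with the length and GC trend removed, with both, within the Ttr levels, and with camera without a variance trend.

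Counts are given in the order PFOS P1-7 against control, PFOS P8-14 against control, and PFOS P8-14 against PFOS P1-7, and their main values are 0, 0 and 0 genes, 7, 13 and 9 lists, and 52, 49 and 10 Reactome pathways. Pseudocounts of 0.1 and 5 kept the called lists on their side of the threshold, and each scaling kept the sign of all 173 named differences. Array weights called 2914 and 1053 genes against control and 1532 across the 3 groups, with 144, 104 and 28 pathways. An estimated correlation and fry each left 0 lists and 0 pathways in all 3 comparisons. Quantile normalization gave 13 lists in the first comparison, with 102, 90 and 0 pathways. Median-of-ratios scaling gave 106 pathways in the first comparison, and fitting only the compared groups gave 21 in the last. In the last comparison no filter gave 0 pathways and a filter at 5 TPM gave 19. With the replicate number as a block, genes stayed at 0 in limma (3112, 2120 and 268 at an unadjusted p below 0.05), with 7, 14 and 10 lists and a correlation of 0.834 between the exposure windows. The labels do not say whether the replicate numbers pair the samples. For these and the changes below, the cause was not tested unless stated.

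Camera without a variance trend gave 5 lists in the last comparison, without the blood, circadian, glycolysis and GABAergic lists. The choroid plexus score as a covariate gave 11, 11 and 7 lists, with 105 pathways in the first comparison and 99 in the second. Removing the length and GC trend gave 30, 28 and 0 pathways and 5 lists in the last comparison. With both, the second comparison had 7 lists and the last 5 pathways. The 4 low-Ttr libraries, with 2 controls and 1 sample of each exposed group, assumed to vary like the controls, gave 15 lists in the first comparison, 4 pathways in the last and a correlation of 0.659. The 5 high-Ttr libraries, with 1 control assumed to vary like the others, called 7 and 1 genes against control, 15 lists in the first and in the last comparison, and 89 pathways in the second.

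Leaving out each library in turn gave 0 to 2658, 0 to 1741 and 0 to 0 genes, 0 to 1493 genes across the 3 groups, 7 to 12, 8 to 14 and 5 to 13 lists, 33 to 167, 26 to 154 and 0 to 32 pathways, and correlations of 0.721 to 0.898. The highest gene counts, pathway counts against control and correlation were without control replicate 1, and 1 gene was called in the first comparison without PFOS P8-14 replicate 1. Of the results for called lists, 205 kept direction and side, 54 lost the call and 2 turned. With 2 samples left, a group is assumed to vary like the others.

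Directions turned as follows. The camera direction of the choroid plexus list in PFOS P8-14 against control turned with its own score as a covariate (median 0.0398), which removes that signal by construction, and with both corrections (0.0574). With both corrections Igf1r and Setd5 in PFOS P1-7 against control were -0.00779 and -0.0452. In the low-Ttr libraries, with 1 sample of each exposed group, S100a9 was 0.67 in PFOS P8-14 against control, and in PFOS P8-14 against PFOS P1-7, which is 1 sample against 1 there, Tac1 was -0.34, Dlx1 -0.0331, Ndufs5 -0.10 and the GABAergic list -0.16. In the high-Ttr libraries, which hold 1 control, PFOS P8-14 against control gave Ccdc153 -0.25, Psmb8 0.00902 and the interferon list 0.36. Without control replicate 2 the interferon list was 0.21 in PFOS P8-14 against control, in a range from -0.47 without control replicate 3 to that value. In PFOS P8-14 against PFOS P1-7, Dlx1 was -0.0165 and Hba-a1 0.17 without PFOS P8-14 replicate 1, against 0.42 without PFOS P8-14 replicate 3 and -4.41 without PFOS P8-14 replicate 2. The ribosomal list was -0.0316 there without PFOS P8-14 replicate 2 and 0.0588 without PFOS P8-14 replicate 1. The cause of these was not tested.

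Depth is unknown, so it is not known which small values it limits. On simulated data the fit recovered 45 to 49.5% of 1.5-fold shifts, so smaller shifts in single genes would often be missed. Those data had no trends between libraries and no shifts in genes of low expression, where recovery was not tested.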

Other observations

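In this part, the choices made only after a result was seen are the variance trend in camera and the sums of alpha-globin copies.

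Lists linked to PFOS biology were not called by camera against control. Over all tested genes the median log2 difference was 0.09 in PFOS P1-7 and 0.06 in PFOS P8-14. Thyroid hormone responsive genes had a median of 0.09 in both exposed groups (adjusted p = 0.771 and 0.528), PPAR target genes 0.17 and 0.14 (0.599 and 0.447), and xenobiotic metabolism genes 0.25 and 0.21 (0.162 and 0.0733). Fatty acid synthesis genes had medians of 0.15 and 0.10 (adjusted p = 0.144 and 0.0639), with 21 and 20 of 22 members higher, and cholesterol biosynthesis genes 0.09 and 0.05 (0.360 and 0.485). NRF2 antioxidant genes had medians of 0.04 and 0.03 (adjusted p = 0.434 and 0.915), ER stress genes 0.06 and 0.01 (0.858 and 0.295), heat shock genes 0.05 and 0.03 (0.862 and 0.876), and glucocorticoid responsive genes 0.11 and 0.17 (0.583 and 0.168). Fry's test of change in either direction, which does not compare a list with other genes, called 10 lists in PFOS P1-7 against control and 0 in the other comparisons. These were CA3 and dentate markers, immediate early, PPAR, xenobiotic, heat shock, cholesterol, fatty acid, microglia and inflammatory genes.

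Glial and vascular lists were not called in PFOS P1-7 against control, where all tested genes had a median of 0.09. Oligodendrocyte and myelin genes had a median of 0.22 with 29 of 31 higher (adjusted p = 0.144), oligodendrocyte precursors 0.14 (0.742), astrocyte markers 0.07 (0.771), endothelial markers 0.01 (0.162) and pericyte markers -0.0009 (0.286). The myelin rise rests largely on control replicate 1, where the list mean was -0.63. It was 0.04 and 0.15 in control replicates 2 and 3, and 0.16, -0.18 and 0.38 in PFOS P1-7 replicates 1, 2 and 3. Neither CA1 (0.07, adjusted p = 0.771), CA2 (0.07, 0.771) nor mossy cell markers (-0.04, 0.308) were called, nor were cell cycle genes (0.01, 0.351), neural stem cell markers (0.06, 0.771), AMPA, kainate and NMDA receptor subunits (0.14, 0.593) and GABA receptor genes (0.17, 0.144). Lists for neighbouring regions, thalamus (0.02, adjusted p = 0.392), neocortex (0.10, 0.771) and striatum (0.12, 0.583), and inflammatory genes (0.04, 0.353) were not called either. The controls differed among themselves in the neocortex list, with 0.40 in control replicate 1 and -0.13 and -0.27 in control replicates 2 and 3. In PFOS P8-14 against control 30 of 43 lists were not called, and in the comparison of exposed groups 34 of 43. The median, mean and test of a list differed in sign for 17, 9 and 13 lists in the 3 comparisons, none of them called.

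Alpha-globin is split between near-identical copies, so Hba-a1 and Hba-a2 were also summed. The sums were 1835, 3078 and 2406 TPM in control, 1349, 1948 and 2615 TPM in PFOS P1-7, and 1515, 1160 and 1191 TPM in PFOS P8-14. Predicted genes at an unadjusted p below 0.05 numbered 151, 104 and 37.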
